A study of Bifidobacterium adolescentis with 8 samples.

How the data were processed

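RNA was sequenced in 8 libraries from Bifidobacterium adolescentis strain P2P3, with 2 libraries for each of 4 carbon sources. Per the labels' protocols, the cells grew without oxygen at 37 °C in 50 mL of medium with 0.5% of the carbon source and were chilled when they entered stationary phase. Total RNA came from 1 mL of culture, ribosomal RNA was depleted with a bacterial mRNA enrichment kit, and TruSeq libraries were read on an Illumina HiSeq instrument. The submitters' processing notes name BWA, SAMtools, Subread and featureCounts, with no version and no order. Strand use, the treatment of reads with several matches and the filters are not given in the sources used here. The labels number the replicates and do not say that they are separate cultures. Every p-value of a comparison between carbon sources is therefore measured against the spread between these samples, which may be technical. The permutation p-values, from random orders of the genes, do not measure that spread.

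The deposited files list, for each library, the same 1715 genes with their chromosome position, a read count and an RPKM value. Positions are on the GenBank chromosome sequence CP024959.1, per the file headers. Per the file headers and the values, the counts are whole reads per gene as the authors counted them, with no normalization. The RPKM deposited beside them equals the count divided by the gene's length in kilobases and by the library's total count, scaled as RPKM is defined. Lengths of 100% of the genes are multiples of 3, so they are coding lengths, from 90 to 9339 bp. Ribosomal and transfer RNA genes are not listed. Genes are identified by locus tags, and 0 of the tags come with a gene name in the files. The 19 gene lists fixed by name and product, with their set tests, could therefore not be applied, and the most abundant genes are represented by the top gene of each group. Neighbouring genes overlap in 199 places, and the reads of overlapping genes are uncertain because the use of strand is not given.

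Read counts were tested with edgeR 4.0.16 in R 4.3.3. A quasi-likelihood F test with robust estimation was fitted to all 8 libraries with 1 mean per group and no replicate term, after TMM normalization. The filter on low counts (filterByExpr) removed 0 of the 1715 genes. The median prior degrees of freedom of the fit were 10.9, beside 4 residual degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each of 6 comparisons, and a gene was called changed at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of its F statistic. Levels are counts per 1000000 reads (CPM) after adjustment of the library sizes by the TMM factors, which ran from 0.685 to 1.23. The test was checked on counts simulated for the 1715 genes from the mean GLC levels at each library's total. In 1 group 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold, far fewer than were called in the data. The simulated RS libraries lacked the large share of reads that 4 genes took in the real ones. Their other genes had more reads than in the data, so the shares for RS do not describe the real comparison at its depth. In simulated RS against GLC it recovered 74.6% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 95.5% of those changed 4-fold, and 6.15% of its calls were false. In simulated GRS against GLC the recovered shares were 92.5%, 100% and 100%, with 2.99% of the calls false. In simulated SS against GLC they were 97.0%, 100% and 100%, with 4.35% of the calls false.

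Genes to be named were chosen by a rule set before the data were examined: adjusted p under 0.05, an average log2 CPM of at least 3, both libraries of one group above both of the other, and the largest fold changes. Without gene names that rule allows 2 genes that rose and 2 that fell per comparison. A second unit of description was added after the counts were seen. A run was defined as 4 or more neighbouring genes, all called the same way with at least a 2-fold change. The longest and the most changed runs of the 4 main comparisons were merged into 19 regions of 224 genes, lettered A to S by position. The regions were chosen on the same samples, so their counts of changed genes are descriptions and not independent evidence. Runs were compared with 1000 random orders of the genes. Such orders break every tie between neighbours, including reads that overlapping genes may share. Their permutation p therefore shows only that neighbours do not change independently. Overlaps between comparisons were set beside 50 simulations of unchanged groups.

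Other settings fixed in advance were DESeq2-style size factors, DESeq2 1.42.0, no filter on low counts, only the 4 libraries compared, the replicate number as a block, and each library left out in turn. Settings added after the data were seen were library totals without scaling, upper-quartile factors, omission of 4 equal-length genes with matching counts, omission of the RS libraries, thinning of all libraries to 190248 reads outside those 4 genes (11 draws), and subtraction of a uniform background from the RS counts. Intervals of shares are 95% Wilson intervals, and the floor of a count of 0 is 3 reads, or 2.43e-05% to 0.000702% of a library's reads. Both cover counting error only.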

Results

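The transcripts of Bifidobacterium adolescentis P2P3, a bacterium of the human gut, were measured by RNA-seq after growth on 4 carbon sources, with 2 libraries each. Glucose (GLC) is a simple sugar. The others were soluble starch (SS), resistant starch (RS), which is the starch that escapes digestion in the small intestine, and gelatinized resistant starch (GRS), in which heating in water has opened the granules. The comparisons ask how transcript levels differ between growth on each starch and growth on glucose, and between the starches. The counts of listed genes summed to 12336412 and 10556223 reads on GLC, 12152207 and 11502382 on SS, and 10305326 and 10762499 on GRS. The RS libraries held 471448 and 427433 reads. On RS 5 and 10 genes had no read, and 198 and 274 of the 1715 genes had fewer than 10 reads.

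Most RS reads came from 4 short genes of equal length at 4 places on the chromosome, starting at 1711479, 1997368, 2094309 and 2174068. Their reads made up 50.7% (95% Wilson interval 50.6 to 50.9%) of the first RS library and 55.5% (55.3 to 55.6%) of the second. The same genes held 0.182% and 0.199% of the reads on GLC, 0.0305% and 0.0375% on SS, and 0.220% and 0.224% on GRS. Outside them the RS libraries held 232256 and 190248 reads. The 4 genes were picked out by a search for genes of equal length whose counts agree within sampling noise in at least 7 libraries. Their sequences were not compared, and the level of each single gene is uncertain because reads shared between them were not ruled out.

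**Figure D1:**
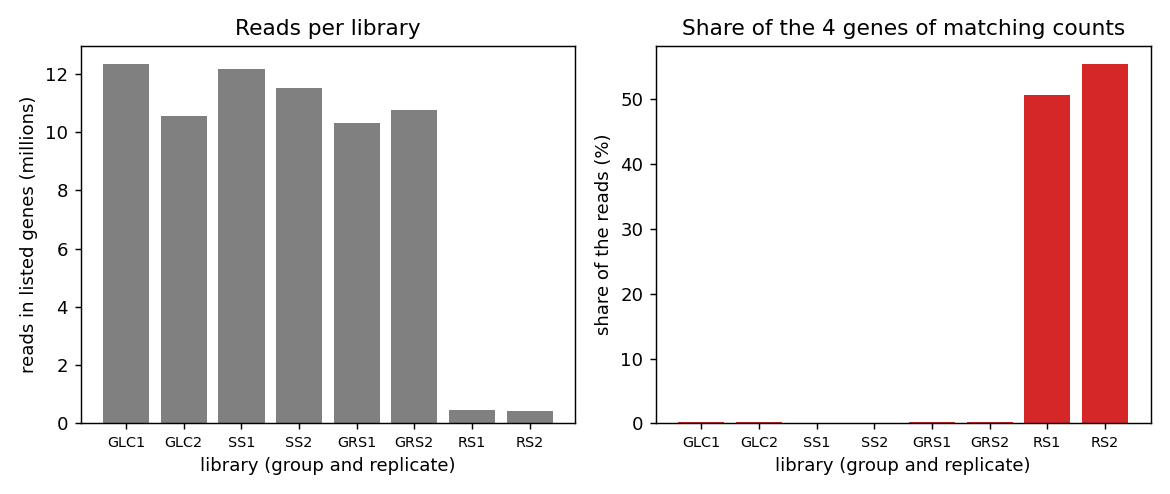
Bars on the left give the reads in listed genes, in units marked on the axis, for each of the 8 libraries, and bars on the right give the percentage of those reads in the 4 genes of matching counts. The RS libraries hold 471448 and 427433 reads, and the 4 genes take 50.7% and 55.5% of them.

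Replicates ranked the genes alike. Spearman's rho across genes, which are not independent replicates, was 0.998 between the GLC libraries, 0.998 between the SS libraries, 0.996 between the GRS libraries and 0.968 between the RS libraries. Between GLC, SS and GRS libraries it lay from 0.853 to 0.878. RS libraries correlated with GLC at 0.668 to 0.692, with GRS at up to 0.709 and with SS at 0.740 to 0.750. The most abundant gene by mean deposited RPKM was CV760_01860 on GLC at 31438 ± 814 (SD, n = 2), CV760_08985 on SS at 38037 ± 1650, CV760_07520 on GRS at 30586 ± 1574 and CV760_08520, one of those 4 genes, on RS at 661631 ± 38890. Apart from SS these were near ties. The next gene was CV760_01885 on GLC at 30461 ± 518 and CV760_00220 on GRS at 30385 ± 6585. On RS the 4 genes lay from 659405 to 661631.

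On resistant starch against glucose, a stretch of 6 genes from 1455900 to 1462100 (region K) rose most among the 19 regions, with a median log2 fold change of 6.10 and all 6 genes higher. Its summed level went from 82.3 ± 0.816 CPM on GLC to 13504 ± 1094 CPM on RS (SD, n = 2). It contains CV760_06445 (1457969 to 1459021), the gene with the largest increase under the naming rule, from 5.53 ± 1.01 to 3730 ± 762 CPM. Regions C, S, H and N also rose in every gene, with medians of 4.15 (7 genes, 193102 to 197542), 3.79 (6 genes, 2161058 to 2170110), 2.87 (10 genes, 1117362 to 1132191) and 2.70 (11 genes, 1687869 to 1700359), although with library totals 9 genes of region N were called higher and 1 lower. All 22 genes of region J, from 1343644 to 1363728, were higher, with a median of 2.24. Among the regions that fell, all 24 genes of region F (429393 to 444374) were lower, with a median of -1.97, and their summed level went from 117904 ± 825 to 31077 ± 1147 CPM. All 4 genes of region O (1715688 to 1719585) were lower, with a median of -4.77, and so were the 4 genes of region D (235875 to 240660), with a median of -3.04, and the 11 genes of region P (1893466 to 1903627), with a median of -1.82.

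Of the 1715 genes, 1342 (78.3%) differed between RS and GLC by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 718 higher and 624 lower. At least 2-fold changes were found in 967 genes, 535 higher and 432 lower. Runs of 4 or more neighbours changed the same way held 436 genes in 67 stretches, against a mean of 70.6 genes in random gene orders (one-sided permutation p = 0.001, the smallest that 1000 orders can give). CV760_06445 had a log2 fold change of 9.40 ± 0.16 (SE; edgeR adjusted p = 4.27e-16), and CV760_08860, one of the 4 genes of matching counts, of 8.89 ± 0.20 (edgeR adjusted p = 3.62e-15). CV760_07515 (1715688 to 1717043) fell by 5.64 ± 0.19 on the log2 scale (edgeR adjusted p = 6.17e-13), from 1984 ± 93.3 to 39.1 ± 7.05 CPM. Its neighbour CV760_07520 (1717116 to 1717322) had 2 and 3 reads on RS, a level 72.3-fold lower than on GLC with a counting interval of 31.0 to 223 (exact, 95%; edgeR adjusted p = 4.76e-11). With every library thinned to the RS depth, 5 genes of region J and 3 of region C were called higher. With library totals in place of TMM factors 34.1% of the changed genes were higher, against 53.5% with TMM.

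On gelatinized resistant starch against glucose, 16 of 16 genes of region R (2039460 to 2066785) rose, with a median log2 fold change of 3.61, and their summed level went from 4555 ± 83.6 to 58199 ± 6676 CPM (SD, n = 2). All 6 genes of region A (45193 to 52833) rose, with a median of 4.52, from 911 ± 71.0 to 19090 ± 3673 CPM (SD, n = 2). All 7 genes of region C rose with a median of 4.08, all 6 of region K with a median of 3.40, and 10 of 11 genes of region M (1582551 to 1595334) with a median of 3.68. The remaining gene of region M was called lower. In region O 3 of the 4 genes rose and 1 fell, and the summed level went from 4337 ± 161 to 36493 ± 1827 CPM. All 7 genes of region E (338922 to 355635) fell, with a median of -1.96, as did all 8 genes of region I (1223812 to 1232059), with a median of -1.75.

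By edgeR's quasi-likelihood test 1403 genes differed between GRS and GLC, 690 higher and 713 lower. Changes of at least 2-fold were more often increases, with 380 genes higher and 170 lower. Changes of at least 4-fold were found in 124 higher and 10 lower genes. CV760_07940 (1841220 to 1844879) rose by 5.86 ± 0.11 on the log2 scale (edgeR adjusted p = 2.07e-15), from 102 ± 4.70 to 5940 ± 292 CPM. CV760_07020 (1592932 to 1593354), in region M, rose by 5.76 ± 0.12 (edgeR adjusted p = 7.11e-15). The neighbours CV760_01415 and CV760_01410 in region E had log2 fold changes of -3.38 ± 0.09 and -3.19 ± 0.09 (edgeR adjusted p = 4.47e-14 and 8.09e-14). Runs of neighbours held 264 genes, against a mean of 14.6 in random orders (one-sided permutation p = 0.001, the smallest possible). At the RS depth 727 genes were called changed, and 3 genes of region C were called higher.

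On soluble starch against glucose, all 53 genes of region G (844886 to 884595) rose, with a median log2 fold change of 2.39, from 2503 ± 14.5 to 21372 ± 990 CPM in sum (SD, n = 2). Of these genes 52 also rose on GRS, with a median of 1.61, and 44 on RS, with a median of 1.90, and no gene of the region was called lower with TMM. With library totals 31 of the genes were called higher on RS and 4 lower. In region M 9 of 11 genes rose and 2 fell, with a median of 3.92, and in region R 14 of 16 rose with a median of 1.69. In region E 6 of 7 genes rose with a median of 2.26, and the summed level went from 18147 ± 351 to 89109.8 ± 5217 CPM. All 5 genes of region B (156185 to 163779) fell with a median of -2.87, all 4 of region L (1517878 to 1523562) with a median of -2.17, and 23 of the 24 genes of region F with a median of -1.01. The remaining gene of region F was called higher, with a log2 fold change of 2.42.

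By edgeR's quasi-likelihood test 1368 genes differed between SS and GLC, 684 higher and 684 lower, and 582 differed at least 2-fold, 357 higher and 225 lower. CV760_05715 (1290280 to 1291647) rose by 7.34 ± 0.11 on the log2 scale (edgeR adjusted p = 1.92e-16), from 33.5 ± 0.482 to 5418 ± 442 CPM. CV760_07940, the gene that rose most on GRS under the naming rule, rose by 6.15 ± 0.11 on SS (edgeR adjusted p = 6.10e-16). CV760_05565 (1248473 to 1249909) fell from 6737 ± 130 to 636 ± 102 CPM, a log2 fold change of -3.40 ± 0.12 (edgeR adjusted p = 2.63e-13), and CV760_00615, of 90 bp in region B, had a log2 fold change of -3.02 ± 0.12 (edgeR adjusted p = 1.18e-12). Runs of neighbours held 223 genes, against a mean of 12.5 in random orders (one-sided permutation p = 0.001, the smallest possible). At the RS depth 777 genes were called changed, and in region G 36 genes were called higher on SS and 33 on GRS. With library totals in place of TMM factors 35.9% of the changed genes were higher on SS, against 50% with TMM.

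**Figure D2:**
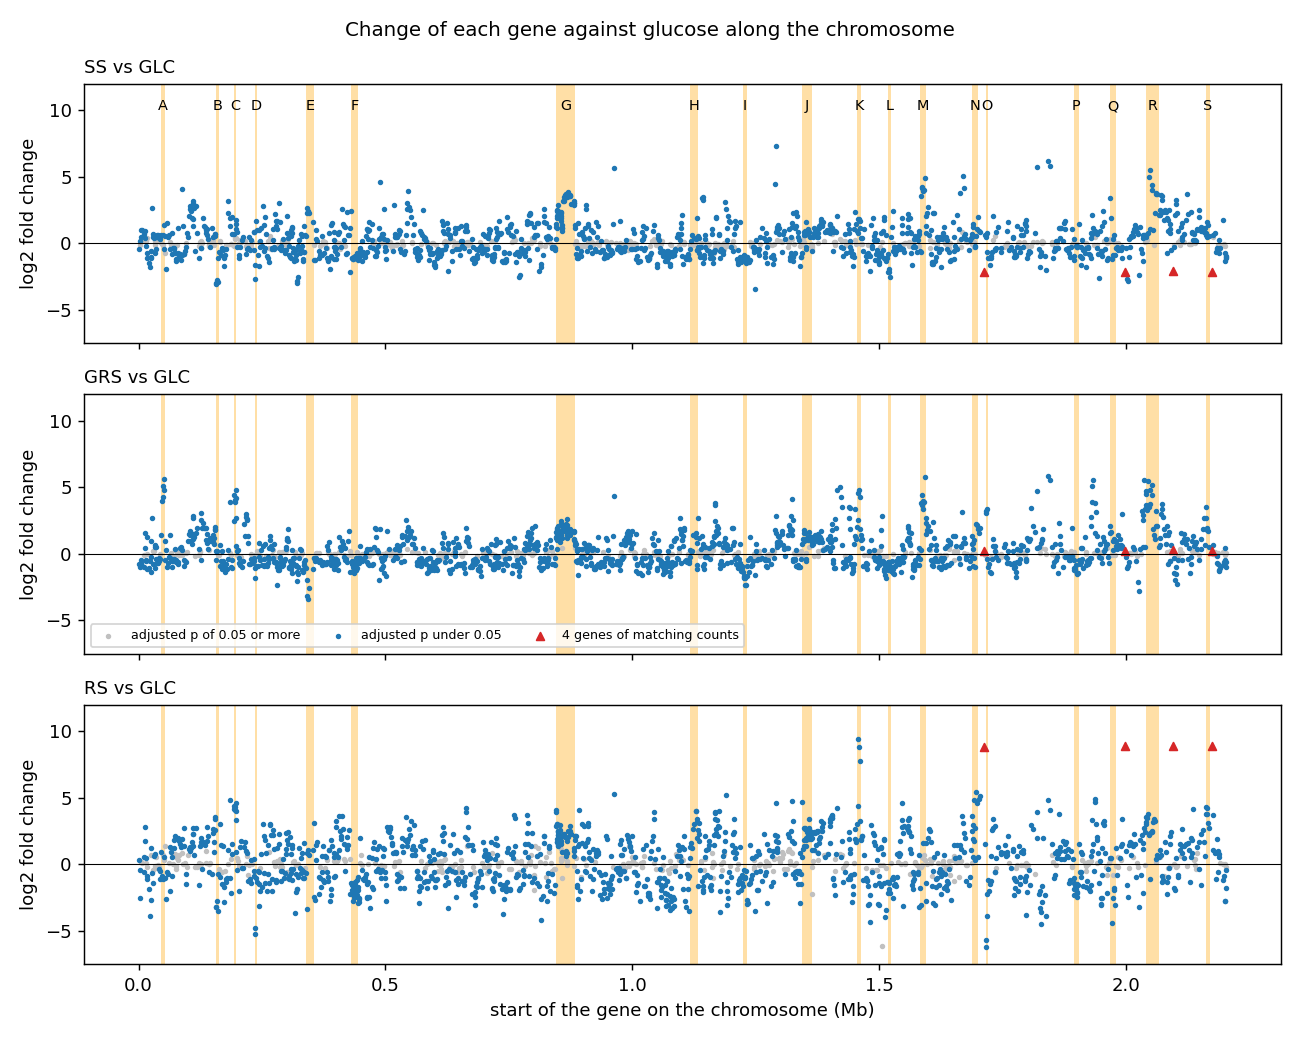
Each point is a gene, with its start on the chromosome in Mb on the horizontal axis and its log2 fold change against glucose on the vertical axis, for SS, GRS and RS from top to bottom. Blue points have an adjusted p under 0.05, grey points do not, and red triangles are the 4 genes of matching counts. Orange bands mark the 19 regions A to S, and the band of region G holds 53 genes with medians of 2.39 on SS, 1.61 on GRS and 1.90 on RS.

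Resistant starch was compared with its gelatinized form to ask what differs when the starch granule has been opened. All 4 genes of region O were lower on RS than on GRS, with a median log2 fold change of -8.00, and their summed level was 237 ± 7.40 CPM on RS and 36493 ± 1827 CPM on GRS (SD, n = 2). All 6 genes of region A were lower on RS with a median of -4.65, all 11 of region M with a median of -3.35, all 5 of region B with a median of -2.96 and all 9 of region Q (1967227 to 1978546) with a median of -2.73. All 6 genes of region K were higher on RS with a median of 2.70, all 11 of region N with a median of 2.16 and all 10 of region H with a median of 1.52. In region E 5 of 7 genes were higher on RS, with a median of 3.32, and 1 was lower by at least 2-fold. In region C 1 of the 7 genes was called higher with TMM, and with library totals 1 was called higher and 2 lower.

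By edgeR's quasi-likelihood test 1238 genes differed between RS and GRS, 644 higher and 594 lower, and 798 differed at least 2-fold. The largest increases were those of CV760_08520 and CV760_07500, both among the 4 genes of matching counts, at 8.64 ± 0.18 and 8.62 ± 0.18 (edgeR adjusted p = 3.67e-15 and 4.45e-15). CV760_07515 had a log2 fold change of -8.73 ± 0.18 (edgeR adjusted p = 3.67e-15). CV760_07520 was 696-fold lower on RS, with a counting interval of 298 to 2142 (edgeR adjusted p = 2.15e-14). Runs of neighbours held 253 genes, against a mean of 32.1 in random orders (one-sided permutation p = 0.001, the smallest possible). With library totals 27.4% of the changed genes were higher on RS, against 52.0% with TMM.

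Against soluble starch, RS gave 1260 changed genes, 612 higher and 648 lower, by edgeR's quasi-likelihood test. All 6 genes of region K were higher on RS, with a median log2 fold change of 4.90, and all 11 genes of region M and all 4 of region O were lower, with medians of -3.45 and -5.40. CV760_07500 and CV760_08520 had the largest increases, of 11.03 ± 0.20 and 11.02 ± 0.19 (edgeR adjusted p = 4.91e-16 and 4.16e-16). CV760_07515 had a log2 fold change of -6.11 ± 0.19 (edgeR adjusted p = 2.40e-13), and CV760_07520 was 115-fold lower on RS, with a counting interval of 49.4 to 355 (edgeR adjusted p = 7.37e-12). The share of changed genes that were higher on RS was 48.6% with TMM, 35.4% with library totals and 59.7% with upper-quartile factors.

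Gelatinized resistant starch against soluble starch gave 1392 changed genes, 717 higher and 675 lower, by edgeR's quasi-likelihood test. All 6 genes of region A were higher on GRS, with 19090 ± 3673 CPM on GRS and 1694 ± 33.8 CPM on SS in sum (SD, n = 2), and all 5 genes of region B were higher with a median of 2.91. In region E 6 of 7 genes were lower on GRS with a median of -4.22, and the summed level was 3028 ± 48.9 CPM on GRS and 89109.8 ± 5217 CPM on SS. CV760_00215 (51326 to 52228), in region A, was higher by 6.05 ± 0.15 on the log2 scale (edgeR adjusted p = 1.36e-14) and CV760_08645 (2036511 to 2037752) by 4.91 ± 0.13 (edgeR adjusted p = 4.37e-14). CV760_01410 and CV760_01415 in region E had log2 fold changes of -5.83 ± 0.10 and -5.78 ± 0.10 (edgeR adjusted p = 7.39e-16 for both). At the RS depth 760 genes were called changed. The share of changed genes that were higher on GRS was 51.5% with TMM, 66.4% with library totals and 64.8% with upper-quartile factors.

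**Figure D3:**
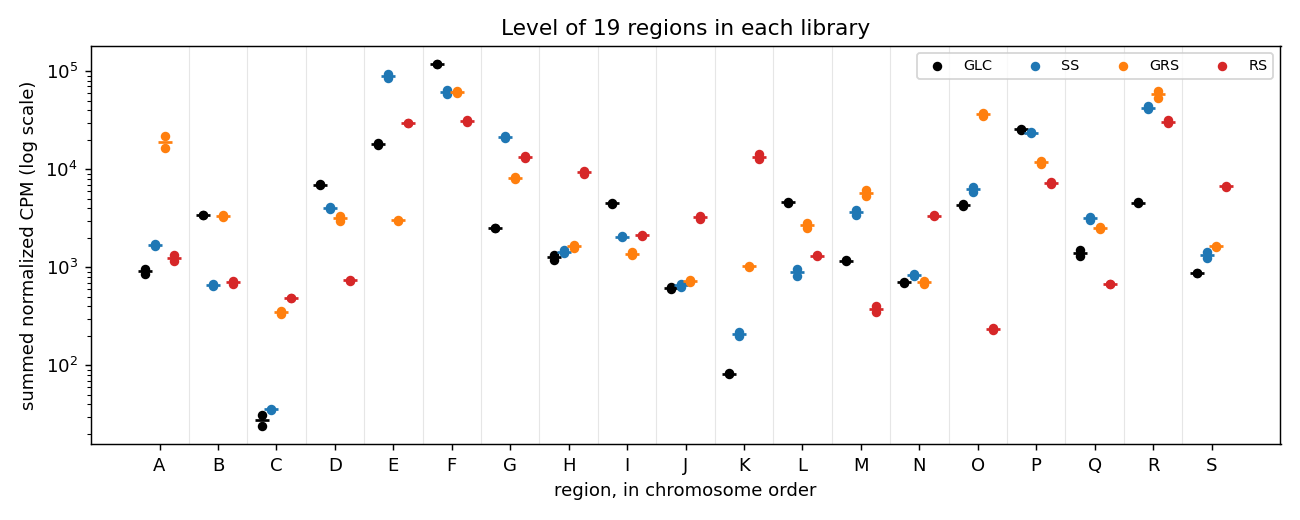
Points give the summed normalized CPM of the genes of each region in each library, on a log scale, and horizontal ticks give the mean of the 2 libraries of a group. Region K runs from 82.3 CPM on GLC to 13504 CPM on RS, and region O from 36493 CPM on GRS to 237 CPM on RS.

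Across the 3 starches, 287 genes were higher than on glucose on all of them and 316 were lower. At a 2-fold threshold these were 117 and 52 genes. RS and GRS shared 443 genes called higher and 429 called lower against glucose, where independent lists would share 289 and 259, and 252 genes were called opposite ways. RS and SS shared 415 and 424, where independent lists would share 286 and 249, and GRS and SS shared 405 and 438, where independent lists would share 275 and 284. Genes called opposite ways numbered 248 for RS and SS and 293 for GRS and SS. With every library thinned to the RS depth, 461 genes were called the same way for RS and GRS, 525 for RS and SS and 388 for GRS and SS. Simulated unchanged groups against the same glucose libraries gave 0 shared calls for each pair, with at most 2 calls in any comparison, so this value does not measure how far shared controls raise the overlap of real changes. The correlation of log2 fold changes across genes was 0.51 for RS and GRS, 0.44 for RS and SS and 0.49 for GRS and SS, where simulated unchanged groups gave 0.14, 0.13 and 0.50. The covariances were 1.15, 1.00 and 0.75, beside simulated covariances of 0.0080, 0.0071 and 0.0078. The 2 glucose libraries are too few to be split with 2 in each part, so part of the excess may come from the shared controls.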

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

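The tests on the 4 genes of matching counts, of depth and of a single fold for region G were chosen after the results were seen. The criterion for a uniform background and that for scaling were set before, although region G was itself picked after the counts were seen.

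Some named genes moved at least 2-fold opposite ways from glucose on 2 starches, and the difference between the starches was itself called by edgeR's quasi-likelihood test. CV760_07520 and CV760_07515 in region O rose on GRS and fell on RS, and RS against GRS differed by -9.44 and -8.73 on the log2 scale. CV760_01410 and CV760_01415 in region E rose on SS and fell on GRS, with differences of -5.83 and -5.78 for GRS against SS. CV760_01415 was also higher on RS than on GLC, by 1.08 with TMM and 0.34 with library totals, and differed by 4.45 between RS and GRS. CV760_01410 was higher on RS by 0.86 with TMM, and with library totals its 0.12 was not called. The genes CV760_07500, CV760_08520 and CV760_08860 rose on RS and fell on SS, with differences of 11.03, 11.02 and 10.98.

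The first pattern is the share of RS reads held by 4 genes of matching counts. Low sequencing depth alone would leave their reads no higher on RS, and their summed reads averaged 14.5 times those of the 6 deeper libraries. Reads shared among near-identical copies stay open: the 4 counts agreed within sampling noise in 8 of 8 libraries (chi-square test), but the genes were found by such agreement, so this decides nothing. All 4 lie among the 10 genes with most bases outside listed genes on their 2 sides, where 3 to 4 locus tags are missing from the list, so leftover transcripts of unlisted sequence around these genes may be the source. A response to RS stays open and untested, since depletion of those transcripts cannot be separated from the carbon source with RS in these 2 libraries alone.

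The second pattern is a narrower range of gene levels on RS, with a standard deviation of log2 read density of 1.93 in both RS libraries. Low depth is argued against, because the lowest value of the deeper libraries thinned to the RS depth still exceeded the highest RS value by 0.159. A narrower range was not particular to RS: at that depth the GRS libraries gave 2.09 and 2.16, and the GLC and SS libraries 2.38 to 2.41. A uniform background such as genomic DNA met the criterion set for it, since subtracting the upper bound of such a background, 4.73% and 4.80% of the reads, widened RS to 2.41. That test decides nothing, because a control added afterwards showed that the same step widened the deeper libraries by 0.366 to 0.800, beside 0.471 and 0.490 on RS. A background and a response to RS therefore cannot be told apart here.

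The third pattern is the rise of region G, near 0.85 Mb, on all 3 starches. The scalings run did not remove the rise: the lowest median log2 fold change over the starches and those scalings was 1.16, although 4 genes were called lower on RS with library totals. The region was picked for its rise with TMM, and a scaling moves all genes of a comparison nearly alike. The result therefore speaks only for the scalings run. The genes' fold changes spread over at least 4.34 times their median SE, which alone would speak against one fold for the whole stretch, as a change in copy number gives. That test cannot exclude a change in copy number combined with changes of single genes. A control added afterwards found a spread of over 3 times the SE in all 1554 other stretches of 53 genes on each starch. Between RS and SS 10 genes of the region were called higher on RS and 26 lower with TMM, from -3.54 to 2.73 on the log2 scale. Both directions were called under every scaling run. These values argue against one fold per starch with no other change. A change in copy number with further changes of single genes and a change in transcription alone cannot be told apart here.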

How the results depend on the processing

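Every named gene kept its direction and its call in the comparison it was named for, under each setting that gives it a value (CV760_08860, CV760_08520 and CV760_07500 have none where the 4 genes of matching counts are left out). These genes were named for the largest fold changes, so this says little about the other calls. Counts of changed genes stayed within 1.5 times under all settings but thinning to the RS depth, which was chosen after the data were seen: it gave 727 for GRS against GLC, 777 for SS against GLC and 760 for GRS against SS, and 461 genes called the same way for RS and GRS, 525 for RS and SS and 388 for GRS and SS. RS against GLC gave 1042 calls at that depth. Thinning moved 12 of the values followed, among them values not listed here, and left 34 the same. Leaving out 1 library, which assumes that the lone sample varies like the other groups, gave 1215 to 1346 genes for RS against GLC, 1312 to 1414 for GRS and 1236 to 1396 for SS. No pairing by replicate number was seen (deviations of the same number correlated at -0.14 to 0.05), which does not exclude a shared batch. With the replicate block 1338, 1386 and 1359 genes changed. Scaling moved the split most. Library totals shifted the median log2 fold change by -0.73 for RS against GLC, -0.71 for RS against GRS, -0.38 for RS against SS, -0.35 for SS against GLC and 0.33 for GRS against SS, with 21 calls reversed in the first and 28 in the second, and increases of at least 2-fold made up 32.2%, 22.4%, 34.7%, 37.8% and 70.5% (55.3%, 51.4%, 50.5%, 61.3% and 50.3% with TMM). Upper-quartile factors gave 63.7% for RS against SS, 46.2% for SS against GLC and 67.8% for GRS against SS. Without the 4 genes of matching counts 96.4% of the RS against GLC calls, 93.3% against GRS and 95.6% against SS were kept, and with a uniform background taken off the RS counts 91.3% (2 reversed), 91.4% and 88.9% (1 reversed). No setting without a filter could differ, since the filter removed 0 genes. Removal of ribosomal and transfer RNA genes and the gene list tests were not run, since neither such genes nor names are listed.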

Other observations

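The starches ordered other regions differently. Region M, higher on SS and GRS, had a median log2 fold change of -0.02 for RS against GLC, whose sign depends on the scaling, with 4 of its 11 genes called lower and 1 higher, all at least 2-fold, and 6 not called. Region B fell on SS and on RS, and on GRS its median was 0.16, with 1 gene lower and 2 called higher, of which 0 were called higher with DESeq2, with library totals or without GLC replicate 1. Region S rose in all 6 genes on each starch, with medians of 0.71 on SS, 1.86 on GRS and 3.79 on RS, and region K rose in all 6 genes with medians of 1.40, 3.40 and 6.10. The medians of both regions kept their direction under every scaling run, while with library totals 2 genes of region S were called higher on SS, and at the RS depth 3 genes of each region were.

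A large-scale trend along the chromosome was tested as a hypothesis, with its criterion set before the result was seen. A replication gradient around the chromosome would give one smooth wave of fold changes, and the first harmonic of position took at most 0.0275 of the variance of the log2 fold changes over the 3 starches, under the limit of 0.05. That highest share, on GRS, exceeded 95% of random orders of blocks of 20 genes (permutation p = 0.03), and blocks were shuffled in place of the shifts planned, because shifts leave the share nearly the same. The shares on RS and SS were 0.00436 and 0.00318. A share under the limit does not exclude a weak gradient, because a share of variance can be small beside the changes of single genes.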
